A study of Homo sapiens with 9 samples.

How the data were processed

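The 9 libraries were made from HCT116 RNA with a TruSeq RNA v2 kit and sequenced on a NextSeq 500, per the submitters' processing notes. Those notes name fastp 0.20.1 for trimming, FastQC 0.11.9 for quality control, STAR without a version for alignment to GRCh38, and DESeq2 1.34.0. The program that made the deposited count table and its annotation release are not given in the sources used here. The count table deposited by the authors holds unnormalised counts per gene and per repeat subfamily, which the notes assign to reads aligned with STAR. The log2 fold changes deposited by the authors come from DESeq2 and are shrunken. The p-values and adjusted p-values deposited by the authors come from DESeq2. The base mean, the mean signal of normalised counts per feature, was computed by the authors with DESeq2 over all 9 libraries.

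The deposited table has 61832 rows: 60651 gene rows and 1181 repeat subfamilies. Of these, 44 are copies of genes on the Y pseudoautosomal region, 22244 gene rows have no symbol, and 58405 have a position in GENCODE v29 on GRCh38. Genes on the Y chromosome and XIST were left out of the texts.

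Groups were taken from the sample labels alone. The title of the third VXN library spells the treatment VNN while its treatment label says VXN, and the treatment label was used. The labelled groups were compared with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), with DESeq2 1.42.0 as the alternative tool, after a filter on low counts that left 19488 genes and 914 repeat subfamilies. p-values were adjusted by the Benjamini-Hochberg method over genes and repeats together, and an adjusted p below 0.05 was called.

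Before the labelled comparisons, the fit was tried on counts simulated over 20402 features with the same spread. Each library was drawn independently, and changes were planted in features with a mean of at least 1 CPM. edgeR called 2 of 20202 unchanged features and DESeq2 54. A planted list was found, with 1 of 21 other lists called.

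The 22 gene lists were interferon-stimulated genes, nucleic acid sensing, MHC class I antigen presentation, H3K9 methylation and silencing, WNT targets and intestinal stem cell markers, intestinal differentiation markers, monoamine genes, cholesterol synthesis and uptake, lysosome, integrated stress response, endoplasmic reticulum chaperones, mitosis, DNA replication, p53 targets, hypoxia, NRF2 targets, NF-kB targets and chemokines, immediate early genes, cancer-testis genes, mesenchymal and fibroblast markers, leukocyte and endothelial markers, and epithelial markers. They were written from general knowledge before the values were seen. Lists with at least 5 expressed members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. For the deposited tables, camera ran on the signed statistics of features with a base mean of at least 10. Where called members of a list or repeat set in those tables are given out of a total, that total counts members with an adjusted p. It can be smaller than the list, and reruns could call other members. The estimated correlations came from voom values of the 9 libraries, grouped as in the table columns. Where libraries of a group differ strongly, such an estimate can rise. A list that fails with it is then not shown to be unchanged.

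Named genes of the deposited tables are the 10 highest and 10 lowest among genes with a base mean of at least 47.6, which equals a mean of 1 CPM. Named repeats and overlap genes passed the same cut-off. Called members of each list were named without it, so some of them may lie below 1 CPM. Symbols without a stable name, antisense names and symbols ending in P and digits, the pattern of pseudogenes, were left out of the 10, which also leaves out some coding genes of that form. Up to 4 members per list were named, by adjusted p, and 5 genes per direction of overlap, by the smaller of the 2 changes. The rule's condition that groups do not overlap was not applied, because those tables hold no samples. It gave 126 named features for shCTRL V and 57 for shDAT D. DDX58 is the tables' older symbol for RIGI. Some named items are not reported here.

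The columns behind each deposited table were sought by trying all 1680 assignments of 9 libraries to 3 trios and correlating signed statistics with those deposited, over 15099 genes with a base mean of at least 50. A first score used log2 fold changes for shCTRL V; both scores ranked the same assignment first. The best assignment gave r of 0.888 for shDAT D and 0.927 for shCTRL V, the next 0.780 and 0.924, and the labels ranked 1302. DESeq2 was then rerun on the best assignment and compared p by p at a tolerance of 1e-06. This search used the values, so its trios describe the authors' contrasts and were not used to regroup the samples.

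Pairs of fold changes sharing a control were set beside 20 simulations in which all libraries, controls included, were drawn as unchanged. Exact permutation was used for SLC6A3, which lies below the filter, so that alternatives of filter, tool and block were not run for it. Each call count was compared with the 10 ways of splitting its 6 libraries into 3 and 3. Reruns on the table columns and the library-series covariate were added after the data were seen. So were the tests of patterns, except thinning, library series and overlapping genes.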

Results

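RNA was sequenced from HCT116, an established human colorectal cancer cell line, in 9 libraries that the labels place in 3 groups of 3. One group carried a control short hairpin RNA and received the solvent DMSO (shCTRL DMSO). Another carried a hairpin against SLC6A3, the gene of the dopamine transporter, and also received DMSO (shSLC6A3 DMSO). The remaining group carried the control hairpin and received a treatment abbreviated VXN, which the labels do not spell out (shCTRL VXN). The series title states the purpose as the effect of knocking down the dopamine transporter in these cells. The count table held 60651 gene rows and 1181 subfamilies of repeats, which are transposable elements and related sequences. Total counts were 51.03, 44.58 and 42.12 M (1e6) in shCTRL DMSO replicates 1 to 3. They were 46.43, 60.22 and 52.98 M in shSLC6A3 DMSO and 30.25, 53.47 and 47.59 M in shCTRL VXN. Repeats took between 1.68% and 2.12% of the counts in each library. No label states that the replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

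SLC6A3 (ENSG00000142319.18, GRCh38 chromosome 5, 1392790 to 1445430, minus strand) was at the edge of detection in every library. The libraries labelled shCTRL DMSO held 6, 2 and 2 counts, those labelled shSLC6A3 DMSO held 3, 1 and 0, and those labelled shCTRL VXN held 0, 3 and 2. Mean levels were 0.069 ± 0.040 CPM (counts scaled to library size; SD, n = 3) in shCTRL DMSO, 0.028 ± 0.034 CPM (SD, n = 3) in shSLC6A3 DMSO and 0.032 ± 0.029 CPM (SD, n = 3) in shCTRL VXN. A count of 0 allows up to 3 counts, or 0.0575 CPM in shSLC6A3 DMSO replicate 3 and 0.0982 CPM in shCTRL VXN replicate 1, counting error only. A two-sided exact permutation test gave p = 0.3 for the shSLC6A3 difference of -0.041 CPM and p = 0.4 for the VXN difference of -0.036 CPM, where 3 libraries against 3 allow no p below 0.1. Without shCTRL DMSO replicate 1 these differences became -0.018 and -0.014 CPM, and without shCTRL VXN replicate 1 the VXN difference became -0.020 CPM. The mRNA therefore gave no check of the labels at this depth.

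The libraries did not group by their labels. Over 11968 genes, Pearson's r of log2 CPM exceeded 0.99 within 3 sets of libraries, 2 of which run across the labelled groups (genes are not independent replicates). One set held shCTRL DMSO replicates 1 and 2 with shCTRL VXN replicates 1 and 2. Another held shCTRL DMSO replicate 3, shSLC6A3 DMSO replicate 1 and shCTRL VXN replicate 3. The last held shSLC6A3 DMSO replicates 2 and 3. Between shCTRL DMSO replicates 1 and 3, r was 0.897. The counts of every pair differed by more than sampling noise. The chi-square per degree of freedom was lowest, at 1.3, for shCTRL DMSO replicate 3 with shSLC6A3 DMSO replicate 1, followed by 1.45 for shSLC6A3 DMSO replicates 2 and 3. MKI67, a marker of dividing cells, stood at 610, 581 and 74.4 CPM in the libraries labelled shCTRL DMSO. It stood at 73.7, 571 and 576 CPM in those labelled shSLC6A3 DMSO and at 518, 587 and 62.2 CPM in those labelled shCTRL VXN. Libraries are therefore called by their labels below, and what each library received is not inferred from its values.

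**Figure D1:**
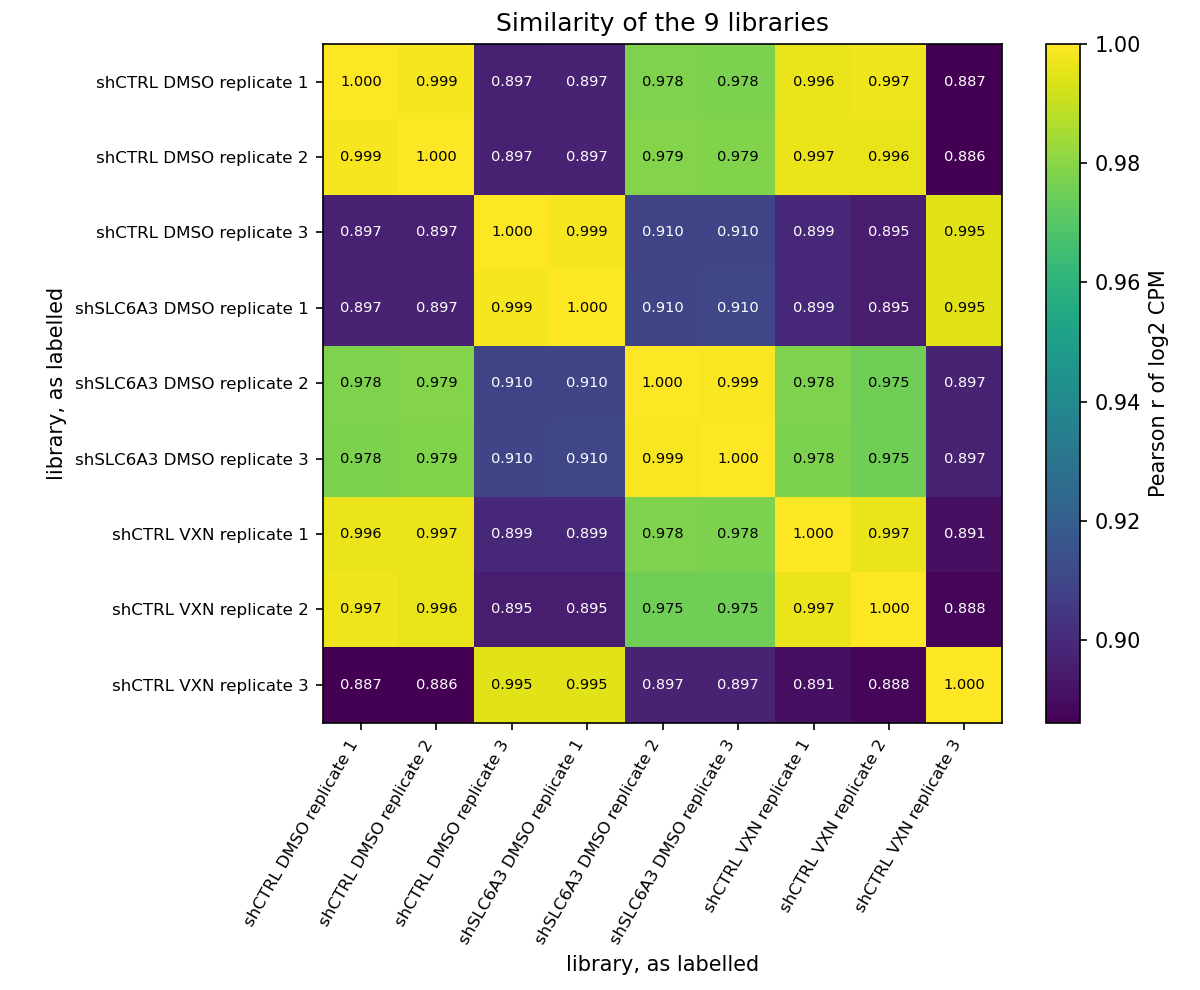
Similarity of the 9 libraries, named by their labels on both axes, as Pearson's r of log2 CPM over 11968 genes (colour and number). Values above 0.99 join libraries within and across labelled groups, and shCTRL DMSO replicates 1 and 3 have an r of 0.897.

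The authors also deposited 2 tables of differential expression, named shCTRL V against shCTRL D and shDAT D against shCTRL D, where DAT is read here as the dopamine transporter. The labelled groups gave the p-values in the authors' deposited table for shDAT D within 1e-06 for 1.41% of features, and those in the table for shCTRL V for 0%. The 1680 ways to assign 9 libraries to 3 trios were ranked by correlation with the deposited statistics. Apart from the labels, only the best-ranked assignment was compared p by p. That assignment gave all 38907 p-values of each of the authors' deposited tables within that tolerance. In it the shCTRL V columns were those of shCTRL DMSO replicate 3, shSLC6A3 DMSO replicate 1 and shCTRL VXN replicate 3. The shDAT D columns were those of shCTRL DMSO replicates 1 and 2 with shCTRL VXN replicate 1, and the shCTRL D columns those of shSLC6A3 DMSO replicates 2 and 3 with shCTRL VXN replicate 2. Over 19488 genes the log2 fold changes between labelled groups correlated at r = -0.466 with the authors' deposited table for shDAT D and at r = 0.056 with that for shCTRL V. The labels and the tables therefore compare different libraries. Libraries were more alike within the tables' trios, where the lowest r was 0.975 (shSLC6A3 DMSO replicate 3 with shCTRL VXN replicate 2). Within labelled groups the lowest was 0.888 (shCTRL VXN replicates 2 and 3). This bears on which libraries belong together, and the data do not show which of the 2 sources names the treatments rightly. The tables' comparisons and the labelled comparisons are reported separately, each under its own names.

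In the comparison of shCTRL V with shCTRL D, the lists of cholesterol synthesis, integrated stress response, NRF2 targets and NF-kB targets rose, and those of mitosis and DNA replication fell. The authors' deposited table gave 5055 genes higher and 5459 lower at an adjusted p below 0.05, of 23276 with an adjusted p, and 1285 of the higher and 1720 of the lower genes changed at least 2-fold. The highest was KLHDC7B at a log2 fold change of 5.79 (SE 0.26), followed in the authors' deposited table by LCN2, an iron-binding protein of innate defence, at 5.13 (SE 0.56) and CXCL8, a chemokine that attracts neutrophils, at 4.49 (SE 0.20). SPX, SORCS2, TNFRSF9, HMOX1, H3C6, IL21R and IZUMO1 made up the rest of the 10 highest named genes, between 4.39 and 3.57 in the authors' deposited table; H3C6 is a histone gene with near-identical copies and its value is uncertain. At the other end, the authors' deposited table listed ZNF488 at -4.50 (SE 0.30), TMSB15A at -4.30 (SE 0.32), CYP24A1, the enzyme that inactivates vitamin D, at -4.22 (SE 0.28), and the transcription factor MYB at -4.15 (SE 0.26). TERT, the catalytic subunit of telomerase, was at -3.97 (SE 0.31) in the authors' deposited table, and CORO1A, SPOCK3, NRGN, DMRT1 and E2F2 lay between -3.84 and -3.46; TMSB15A has a close paralog and is uncertain. Leaving out any 1 of the 6 libraries left between 4372 and 5413 genes higher and between 4793 and 5851 lower in a DESeq2 rerun.

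Cholesterol synthesis and uptake was the list with the most uniform rise. Of its 25 members, 24 were higher and 0 lower in the authors' deposited table, with a list median of 2.29 on the log2 scale. HMGCS1, which makes the HMG-CoA of the mevalonate pathway (ENSG00000112972.15, GRCh38 chromosome 5, 43289395 to 43313512), was at 2.97 (SE 0.11) in the authors' deposited table, IDI1, an isomerase of the same pathway, at 2.40 (SE 0.08), LSS, which forms lanosterol, at 2.55 (SE 0.09), and SC5D, a late desaturase, at 2.29 (SE 0.08). Of the 23 lysosome genes, 12 were higher and 5 lower in the authors' deposited table. They included SQSTM1, the autophagy receptor p62, at 2.41 (SE 0.10), NPC1, which exports cholesterol from the lysosome, at 1.67 (SE 0.08), NEU1 at 1.73 (SE 0.10) and PSAP at 1.13 (SE 0.07), all from the authors' deposited table. A camera test computed here from the authors' deposited table gave an adjusted p of 9.11e-62 for the cholesterol list and 0.000112 for the lysosome list. With an estimated correlation the adjusted p was 3.47e-06 for cholesterol, and adjusted p = 0.288 with an estimated correlation for the lysosome list. When adjusted over the list alone, 24 cholesterol genes were higher and 12 lysosome genes higher and 6 lower.

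The members of the mitosis and DNA replication lists fell. All 20 members of the mitosis list and all 21 of the DNA replication list were lower in the authors' deposited table, with medians of -2.44 and -2.61 on the log2 scale. MKI67 (ENSG00000148773.14, GRCh38 chromosome 10, 128096659 to 128126385) was at -3.06 (SE 0.09) in the authors' deposited table, BIRC5, an inhibitor of apoptosis needed at mitosis, at -2.49 (SE 0.08), CENPF, a kinetochore protein, at -2.71 (SE 0.09) and the checkpoint kinase BUB1 at -2.54 (SE 0.09). Among replication genes, the authors' deposited table gave -2.61 (SE 0.08) for RRM1, a subunit of ribonucleotide reductase, -2.21 (SE 0.08) for the helicase subunit MCM7, -3.46 (SE 0.12) for E2F2 and -2.72 (SE 0.11) for E2F1. Of 20 p53 targets, 13 were higher and 1 lower in the authors' deposited table. CDKN1A, which halts the cell cycle, was at 1.49 (SE 0.09) there, the death receptor gene TNFRSF10B at 1.83 (SE 0.06), TP53INP1 at 2.07 (SE 0.12) and TP53I3 at 1.59 (SE 0.09), all in the authors' deposited table. The camera test on the authors' deposited table gave adjusted p-values of 1.82e-65 for mitosis, 1.05e-46 for DNA replication and 2.91e-06 for p53 targets. These were 1.66e-05, 0.000338 and 0.000279 with an estimated correlation. When adjusted over the list alone, 20 mitosis and 21 replication genes were lower, and 14 p53 targets were higher and 1 lower. Without shCTRL VXN replicate 2, 2 p53 targets were lower.

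Stress and inflammatory genes rose in the same comparison. In the authors' deposited table, 18 of 22 integrated stress response genes were higher and 0 lower. They included SESN2 at 2.05 (SE 0.07), the secreted factor GDF15 at 2.58 (SE 0.11), CHAC1, which degrades glutathione, at 1.88 (SE 0.10) and the transcription factor DDIT3 at 1.93 (SE 0.11) in the authors' deposited table. Of 16 NRF2 targets, genes of the antioxidant response, 12 were higher and 1 lower in the authors' deposited table. HMOX1, the heme-degrading enzyme (ENSG00000100292.18, GRCh38 chromosome 22, 35380361 to 35394214), was at 3.81 (SE 0.08), OSGIN1 at 2.34 (SE 0.11), SRXN1 at 1.62 (SE 0.11) and GCLC, a subunit of the first enzyme of glutathione synthesis, at 1.62 (SE 0.13), by the authors' deposited table. Of 13 NF-kB targets and chemokines, 11 were higher and 0 lower in the authors' deposited table, with RELB at 1.23 (SE 0.08), NFKBIA at 0.94 (SE 0.08) and CXCL1 at 2.56 (SE 0.28). The authors' deposited table had 10 of 18 endoplasmic reticulum chaperone genes higher and 2 lower, with the chaperone HSPA5 at 1.59 (SE 0.10), DNAJB9 at 1.90 (SE 0.12), SEL1L at 1.35 (SE 0.08) and HERPUD1 at 1.14 (SE 0.07). Adjusted camera p-values from the authors' deposited table were 4.81e-10 for the integrated stress response, 5.06e-08 for NRF2 targets, 7.53e-06 for NF-kB targets and 0.000113 for chaperones. With an estimated correlation they were 0.00766, 0.0131 and 0.0131 for the first 3 lists, and adjusted p = 0.324 with an estimated correlation for the chaperones. With p adjusted over the list alone, 19 integrated stress response genes, 12 NRF2 targets and 11 NF-kB targets were higher, 1 NRF2 target was lower, and 10 chaperone genes were higher and 3 lower. Without shCTRL VXN replicate 2, 2 NRF2 targets and 6 chaperone genes were lower, and without any other single library 1 chaperone gene was.

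More members of the H3K9 silencing list and of the WNT and stem cell list were lower than higher. EHMT2, the histone H3K9 methyltransferase also called G9a (ENSG00000204371.11, GRCh38 chromosome 6, 31879759 to 31897687), was at -0.82 (SE 0.07) with an adjusted p of 3.17e-27 from DESeq2 in the authors' deposited table. Of the 24 genes of H3K9 methylation and silencing, 14 were lower and 5 higher in the authors' deposited table. Members with the lowest adjusted p included HELLS, a chromatin remodeler, at -2.99 (SE 0.14) and SUV39H1, another H3K9 methyltransferase, at -2.11 (SE 0.11). They also included the maintenance DNA methyltransferase DNMT1 at -1.61 (SE 0.08) and the demethylase KDM1A at -0.88 (SE 0.05), as the authors' deposited table gives them. Of 20 WNT targets and intestinal stem cell markers, 11 were lower and 1 higher in the authors' deposited table, with DKK1, a secreted WNT antagonist and WNT target, at -3.22 (SE 0.18), MYC at -0.82 (SE 0.08) and MSI1 at -0.75 (SE 0.08). Both lists passed the camera test on the authors' deposited table, with adjusted p-values of 2.01e-05 and 0.00292, and neither passed with an estimated correlation (adjusted p = 0.0561 with an estimated correlation for each). Adjusted over the list alone, the counts were 5 higher and 14 lower for H3K9 and 1 higher and 11 lower for WNT. The 5 higher H3K9 genes became 1 without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1 and 3 without any other single library. The 1 higher WNT gene became 2 without shSLC6A3 DMSO replicate 2 or 3 or shCTRL VXN replicate 2.

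Immune sensing lists moved in both directions. The authors' deposited table had 9 interferon-stimulated genes higher and 11 lower of 36, with the antiviral gene OAS3 at -2.00 (SE 0.12), HERC5 at -0.98 (SE 0.10), IRF7 at 1.45 (SE 0.11) and ISG20 at 1.89 (SE 0.21). For nucleic acid sensing 4 of 14 were higher and 1 lower in the authors' deposited table, among them TRIM25 at 0.93 (SE 0.05) and DDX58, the RNA sensor RIG-I, at 0.57 (SE 0.13). In antigen presentation by MHC class I 5 were higher and 6 lower of 18 in the authors' deposited table, such as ERAP1 at 0.95 (SE 0.14) and PSMB10 at -0.95 (SE 0.15). Of 18 hypoxia genes, 4 were higher and 10 lower in the authors' deposited table, with the angiogenic factor VEGFA at 2.14 (SE 0.07) and lactate dehydrogenase LDHA at -1.65 (SE 0.07). None of these 4 lists passed the camera test on the authors' deposited table (adjusted p of 0.774, 0.172, 0.980 and 0.663). When adjusted over the list alone, 9 interferon-stimulated genes were higher and 11 lower, 4 sensing genes higher and 1 lower, 5 antigen presentation genes higher and 7 lower, and 4 hypoxia genes higher and 10 lower. Without shSLC6A3 DMSO replicate 1, or without shCTRL VXN replicate 3, 6 hypoxia genes were lower.

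Epithelial markers held 8 changed genes, and the other cell identity lists and the dopamine-related list 6 or fewer each, in the authors' deposited table. In the authors' deposited table, 7 of 13 epithelial markers were higher and 1 lower, including E-cadherin (CDH1) at 1.04 (SE 0.07) and the splicing factor ESRP1 at 1.12 (SE 0.07). Intestinal differentiation markers had 3 of 10 lower and 0 higher in the authors' deposited table, namely CA2 at -1.64 (SE 0.09), HPGD at -2.72 (SE 0.93) and KRT20 at -0.76 (SE 0.27). Of 9 monoamine genes, 2 were higher and 3 lower in the authors' deposited table, with the dopamine-degrading oxidase MAOB at -0.75 (SE 0.07) and the dopamine receptor DRD1 at -1.42 (SE 0.33), while SLC6A3 was at 0.13 (SE 0.51) with no adjusted p. The authors' deposited table had 3 mesenchymal and fibroblast markers higher and 3 lower of 14, with COL6A3 at 1.86 (SE 0.27) and FN1 at -1.75 (SE 0.44). It also had 1 of 11 leukocyte and endothelial markers lower (CSF1R, -1.30, SE 0.82, in the authors' deposited table). Of 6 cancer-testis genes, 1 was higher and 2 lower in the authors' deposited table, with PRAME at -0.81 (SE 0.13); too few were expressed for a list test. Of the 17 immediate early genes, which answer growth signals within minutes, 11 had an adjusted p in the authors' deposited table. Of these, 3 were higher and 2 lower there, such as SPRY4 at 0.72 (SE 0.11) and NR4A1 at -1.58 (SE 1.40). Only the epithelial list passed the camera test on the authors' deposited table (adjusted p of 0.00593), and it did not with an estimated correlation (adjusted p = 0.127 with an estimated correlation). The adjusted p was 0.167 for differentiation, 0.713 for monoamine, 0.774 for mesenchymal, 0.980 for leukocyte and 0.592 for immediate early genes, and the medians of the mesenchymal and leukocyte lists (-0.0042 and 0.0082) have the opposite sign to their test. Adjusted over the list alone, the counts were 8 higher and 1 lower for epithelial, 3 lower for differentiation, 2 higher and 3 lower for monoamine, 3 higher and 3 lower for mesenchymal, 0 for leukocyte, 1 higher and 2 lower for cancer-testis, and 3 higher and 2 lower for immediate early genes. Without shCTRL VXN replicate 2, in which FOS stood at 508 CPM against 4.40 and 4.06 CPM in the other shCTRL D columns, 11 immediate early genes were higher and 1 lower, and 6 mesenchymal and 2 leukocyte markers were higher. Without that library 2 epithelial markers were lower and 1 differentiation marker higher. The immediate early counts were 2 higher and 1 lower without shCTRL DMSO replicate 3, 2 and 0 without shSLC6A3 DMSO replicate 1, 2 and 5 without shSLC6A3 DMSO replicate 2 or 3, and 3 and 0 without shCTRL VXN replicate 3. The higher cancer-testis gene was lost without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1 or 2. The lower leukocyte marker was lost without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1, and 2 were lower without shSLC6A3 DMSO replicate 3.

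**Figure D2:**
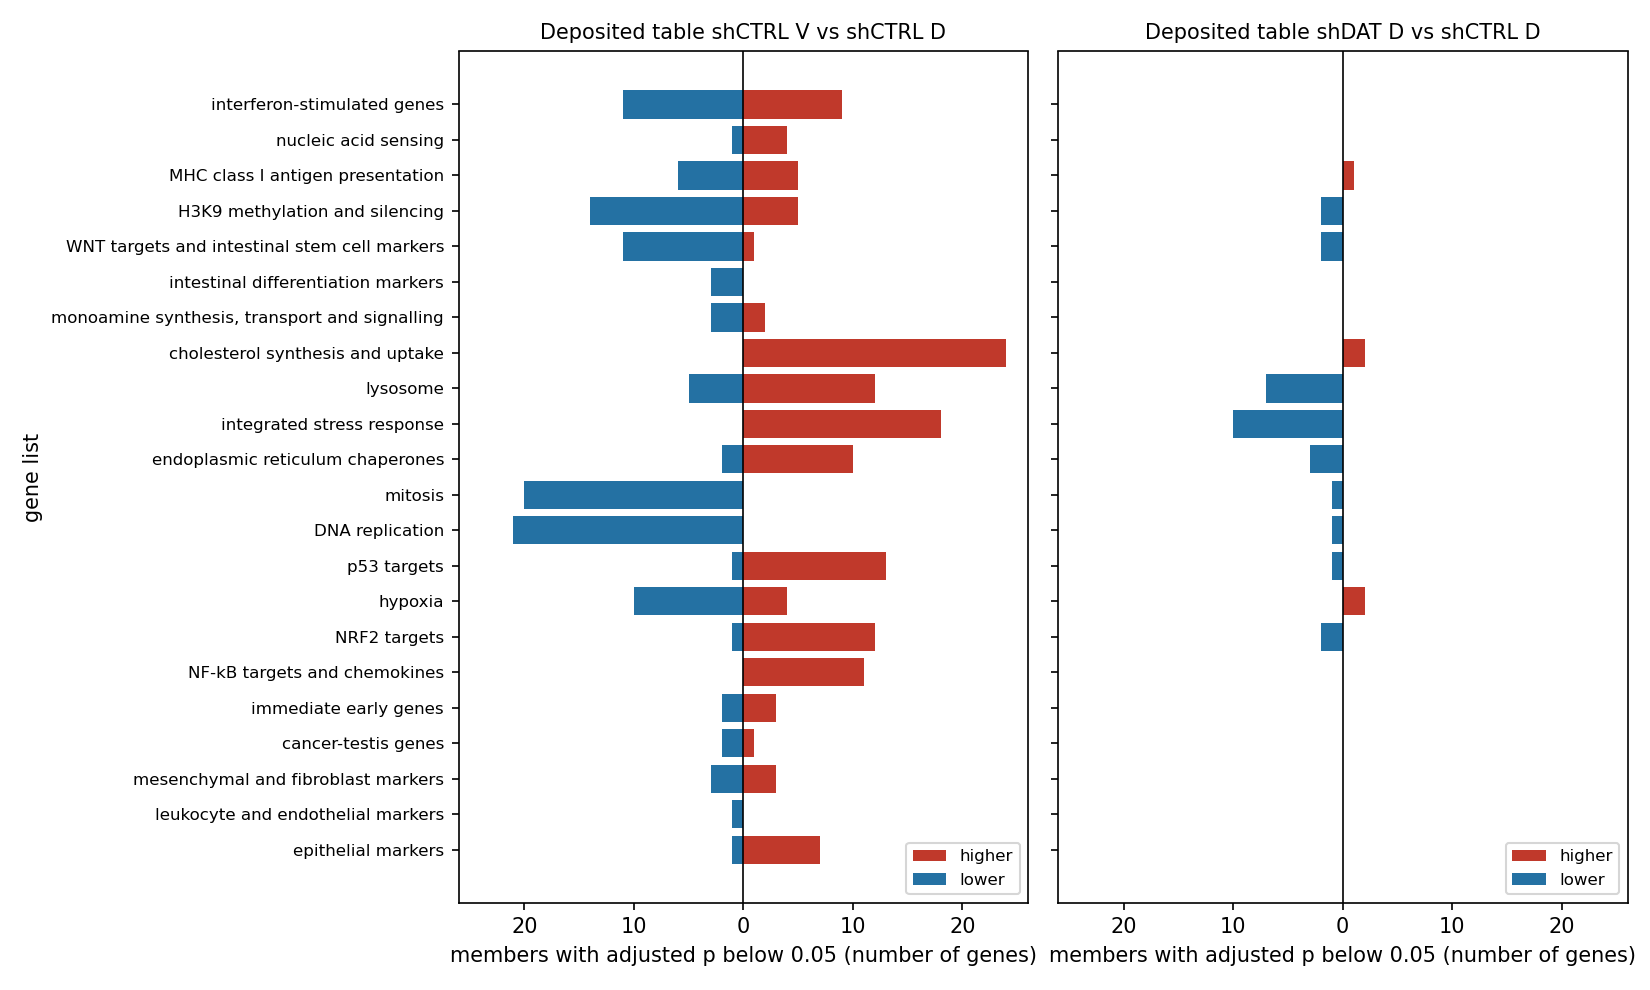
Members of each of the 22 gene lists with an adjusted p below 0.05 in the authors' deposited tables, as numbers of genes higher (right of 0) and lower (left of 0), for shCTRL V against shCTRL D and for shDAT D against shCTRL D. In the authors' deposited table for shCTRL V, 24 cholesterol genes lie to the right and 20 mitosis and 21 DNA replication genes to the left.

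Among repeats, more of the called subfamilies were higher than lower in the shCTRL V comparison. The authors' deposited table had 129 subfamilies higher and 43 lower of 998, with LTR13_ at 2.57 (SE 0.35), LTR48B at 1.84 (SE 0.09), L1M8 at 1.74 (SE 0.37), Charlie8 at 1.73 (SE 0.12) and MER103C at 1.20 (SE 0.09). The lowest in the authors' deposited table were LTR40A1 at -2.07 (SE 0.33), the satellite ACRO1 at -1.21 (SE 0.29), MER4A at -1.17 (SE 0.12), LTR7Y at -1.10 (SE 0.18) and then LTR25. By class, 56 LTR subfamilies were higher and 25 lower in the authors' deposited table, 26 LINE higher and 10 lower, and 16 SINE higher and 0 lower. None of 26 repeat families and classes passed the camera test on the authors' deposited table, with the preset or an estimated correlation. Without shCTRL VXN replicate 2 the count of higher subfamilies was 197, and without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1 that of lower subfamilies was 28. Reads of repeats inside transcribed genes were not separated from those of independent repeat transcripts.

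**Figure D3:**
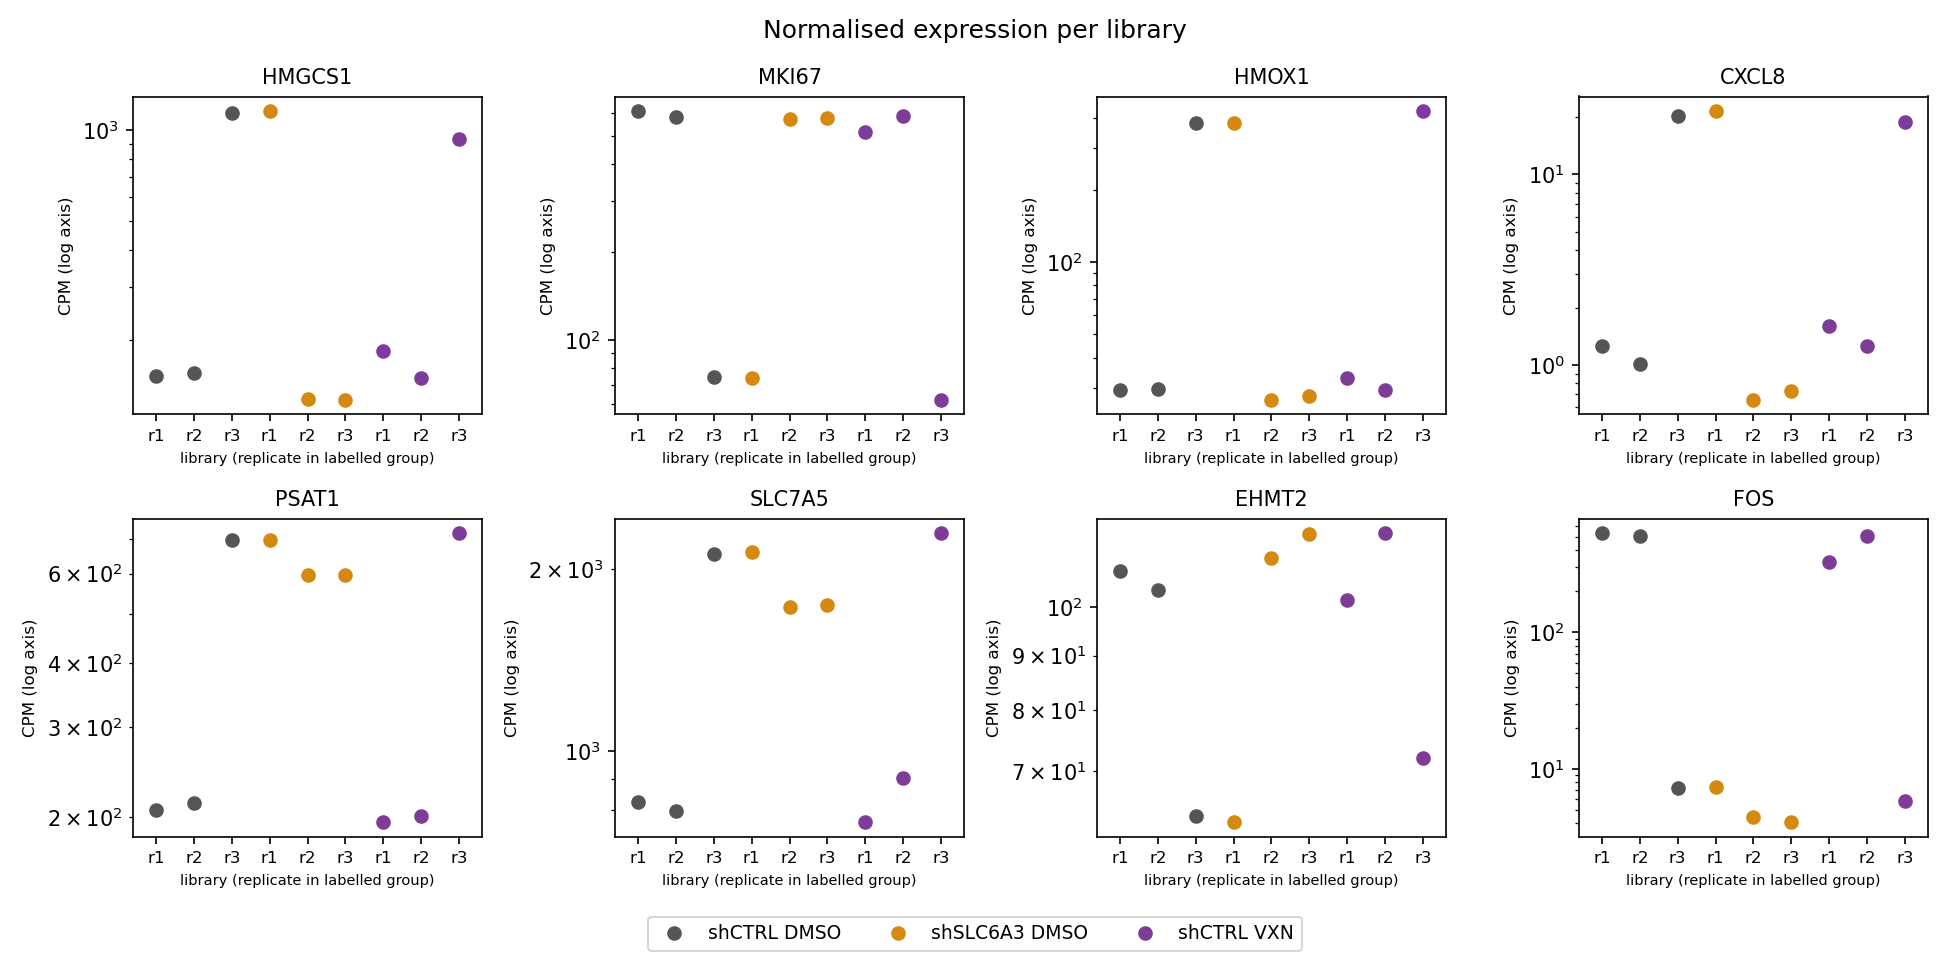
Normalised expression (CPM, log axis) of 8 genes in each of the 9 libraries, in panels by gene, coloured by labelled group and placed by replicate. HMGCS1 lies between 936 and 1159 CPM in shCTRL DMSO replicate 3, shSLC6A3 DMSO replicate 1 and shCTRL VXN replicate 3, and between 127 and 184 CPM in the other 6 libraries.

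In the comparison of shDAT D with shCTRL D, more genes were lower than higher, by less than 2-fold in nearly every case. The authors' deposited table had 96 genes higher and 584 lower of 10211 with an adjusted p, and 0 of the higher and 3 of the lower changed at least 2-fold. The authors' fold changes are shrunken. The median ratio to an unshrunken estimate was 0.545 for the authors' deposited table of shDAT D and 0.971 for that of shCTRL V. The shCTRL D column shCTRL VXN replicate 2 also resembled the shDAT D columns. Its r was 0.997 with shCTRL DMSO replicate 1 and 0.975 with shSLC6A3 DMSO replicate 2. FOS stood at 535, 509 and 328 CPM in the shDAT D columns. In the shCTRL D columns it stood at 4.40, 4.06 and 508 CPM. Fold changes in this comparison average over these unlike controls, so their small size does not show small differences from each control library. The lowest named genes in the authors' deposited table were CEMIP, a hyaluronan-degrading protein, at -1.05 (SE 0.53), PSAT1, an enzyme of serine synthesis (ENSG00000135069.14, GRCh38 chromosome 9, 78297143 to 78330093), at -0.97 (SE 0.39), the cystine transporter gene SLC7A11 at -0.85 (SE 0.49), and ASNS, asparagine synthetase, at -0.85 (SE 0.41). ANO1, SLC7A5, SLC1A4, PCK2, PHGDH and SNTB1 followed in the authors' deposited table, between -0.85 and -0.75. The highest in the authors' deposited table were the noncoding RNA MIR22HG at 0.72 (SE 0.26), FA2H, which hydroxylates fatty acids, at 0.69 (SE 0.28), RRP7BP, a pseudogene and therefore uncertain, at 0.54 (SE 0.26), and USH1C at 0.52 (SE 0.24). MT-CO2, a mitochondrially encoded respiratory subunit, was at 0.52 (SE 0.12) in the authors' deposited table, and MXD1, GADD45A, C4orf3, SEMA3B and TTLL3 lay between 0.51 and 0.43. SLC6A3 was at 0.01 (SE 0.10) with no adjusted p, and EHMT2 at -0.12 (SE 0.07) with an adjusted p of 0.118 from DESeq2, in the authors' deposited table. These counts rested on single libraries and on the tool: edgeR on the same columns called 0 genes (4097 at an unadjusted p below 0.05). A DESeq2 rerun called 2926 genes higher and 4767 lower without shCTRL VXN replicate 2, 5 and 8 without shCTRL DMSO replicate 1, 0 and 2 without shCTRL VXN replicate 1, and 0 and 0 without shCTRL DMSO replicate 2, shSLC6A3 DMSO replicate 2 or shSLC6A3 DMSO replicate 3. With the library-number series as a covariate, chosen after the data were seen, the rerun called 784 higher and 1510 lower.

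Among the lists, the integrated stress response held the most lower genes in that comparison, 10 of 21 with 0 higher in the authors' deposited table. SLC7A5 was at -0.82 (SE 0.20), its partner SLC3A2, with which it imports large neutral amino acids, at -0.68 (SE 0.18), PHGDH, which starts serine synthesis, at -0.78 (SE 0.21), and STC2 at -0.47 (SE 0.18) in the authors' deposited table. Of 22 lysosome genes, 7 were lower and 0 higher in the authors' deposited table, among them CTSD at -0.31 (SE 0.11) and LAMP1 at -0.31 (SE 0.13). The authors' deposited table had 3 of 18 chaperone genes lower (HYOU1, -0.43, SE 0.16), 2 of 24 H3K9 genes lower (WIZ, a partner of G9a, -0.26, SE 0.12), 2 of 14 NRF2 targets lower and 2 of 15 WNT genes lower (SOX9, -0.40, SE 0.17). Single lower genes in the authors' deposited table were FOXM1 (-0.36, SE 0.14) of 20 mitosis genes, CCNE1 (-0.33, SE 0.14) of 21 replication genes and AEN (-0.21, SE 0.09) of 19 p53 targets. Higher genes in the authors' deposited table were KDM3A (0.32, SE 0.13) and LDHA (0.20, SE 0.07) of 15 hypoxia genes, STARD4 (0.39, SE 0.14) and SQLE (0.22, SE 0.08) of 25 cholesterol genes, and HLA-E (0.26, SE 0.11) of 12 antigen presentation genes. The authors' deposited table called 0 members of the interferon, nucleic acid sensing, differentiation, monoamine, NF-kB, immediate early, cancer-testis, mesenchymal, leukocyte and epithelial lists. Only 10211 of the 37765 genes with a p-value had an adjusted p there. Members without an adjusted p could not be called, so 0 calls do not show that a list was unchanged. With p adjusted over the list alone, the lower counts were 12 for integrated stress response, 9 lysosome, 12 chaperones, 7 H3K9, 6 NRF2, 3 WNT, 5 mitosis, 1 replication and 0 p53. The higher counts adjusted over the list alone were 11 for hypoxia, 3 cholesterol, and 1 each for antigen presentation, differentiation, integrated stress response, NRF2 and WNT, with 0 for the rest. The camera test on the authors' deposited table passed 15 of 21 lists, with adjusted p-values of 1.29e-05 for the integrated stress response, 1.29e-05 for lysosome, 7.69e-06 for chaperones and 5.08e-08 for hypoxia. None of the 21 passed with an estimated correlation: for the 15 that had passed, the adjusted p lay between 0.328 and 0.385 with an estimated correlation. That estimate came from differences within the trios, and shCTRL VXN replicate 2, a shCTRL D column, resembled the shDAT D columns. A list that differs between these trios can therefore fail, and the failure does not show that the lists were unchanged. The other 11 passing with the preset correlation were H3K9 (0.00609), cholesterol (0.0010), NRF2 (0.00875), mitosis (0.000702) and replication (0.000138), and interferon (7.17e-05), differentiation (0.0122), NF-kB (0.0176), immediate early (0.00793), mesenchymal (0.0234) and leukocyte genes (0.0176), by camera on the authors' deposited table. Those not passing there were WNT (0.652), p53 (0.299), antigen presentation (0.553), sensing (0.553), monoamine (0.335) and epithelial genes (0.0664), where the antigen presentation and monoamine medians (-0.02 each) have the opposite sign to their test. Without shCTRL VXN replicate 2, the lower genes numbered 14 for the integrated stress response, 16 lysosome, 17 chaperones, 14 H3K9, 11 NRF2, 7 WNT, 14 mitosis, 10 replication, 4 p53, 6 antigen presentation, 8 epithelial, 3 sensing, 3 cholesterol, 2 interferon, 2 cancer-testis, 1 monoamine and 1 mesenchymal. Without that library the higher genes numbered 14 for hypoxia, 14 immediate early, 16 interferon, 10 cholesterol, 6 p53, 5 each for WNT, NF-kB, antigen presentation and mesenchymal, 4 leukocyte, 3 each for differentiation, H3K9 and the integrated stress response, 2 each for sensing, NRF2 and epithelial, and 1 each for cancer-testis and monoamine. Without shCTRL DMSO replicate 1, 3 integrated stress response genes were lower and 1 cholesterol gene higher. Without any 1 of the other 4 libraries, 0 members of any list were called. Each trio of columns held 1 library of the second number range. With that series as a covariate, chosen after the data were seen, the higher genes numbered 12 for hypoxia, 9 cholesterol, 3 mesenchymal, 2 each for p53, interferon and differentiation, and 1 each for the integrated stress response, WNT, NRF2, NF-kB, antigen presentation, cancer-testis, leukocyte and epithelial genes. The lower genes with that covariate numbered 12 for the integrated stress response, 10 chaperones, 8 lysosome, 8 H3K9, 7 mitosis, 5 NRF2, 4 replication, 3 WNT, and 1 each for p53, immediate early and cancer-testis genes.

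Few repeat subfamilies were called in the shDAT D comparison, and the calls rested on single libraries. The authors' deposited table had 8 subfamilies higher and 1 lower of 192, with L1PA5 at 0.28 (SE 0.10), MER2 at 0.27 (SE 0.08), L1ME4c at 0.24 (SE 0.09), L1ME2 at 0.22 (SE 0.07) and L1ME3G at 0.20 (SE 0.08), and LTR7 at -0.55 (SE 0.22). In the L1 family, 7 of 70 were higher and 0 lower in the authors' deposited table. The camera test on the authors' deposited table passed 16 of 26 families and classes, and 0 with an estimated correlation, where L1 had an adjusted p = 0.136 with an estimated correlation. That estimate has the limit given above for the lists. edgeR called 0 subfamilies on the same columns (158 at an unadjusted p below 0.05). Without shCTRL VXN replicate 2 the DESeq2 rerun called 188 higher and 9 lower, and without any 1 of the other 5 libraries 0 and 0. With the library series as a covariate, chosen after the data were seen, it called 47 higher and 4 lower.

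The 2 comparisons of the authors' deposited tables shared the shCTRL D columns, and genes changed in the same and in opposite directions in them. Of 10206 genes with an adjusted p in both of the authors' deposited tables, 36 were higher in both (29.5 for independent lists) and 205 lower in both (213). Another 204 were lower for shDAT D and higher for shCTRL V in the authors' deposited tables (179), and 36 were higher for shDAT D and lower for shCTRL V (35.0). Higher in both of the authors' deposited tables were MIR22HG (0.72 and 2.35, shDAT D first), MXD1, a MYC antagonist (0.51 and 2.66), the growth arrest gene GADD45A (0.51 and 1.01), SEMA3B and TTLL3. Lower in both of the authors' deposited tables were the copper chaperone ATOX1 (-0.55 and -0.49), TIMM10 (-0.47 and -0.58), TNS4, the chaperone HSPA8 and PRPS1. Opposite in the authors' deposited tables were SLC7A11 (-0.85 and 1.71), SLC1A4 (-0.81 and 1.33), PCK2 (-0.80 and 1.24), SNTB1 (-0.75 and 0.74) and TRIB3, a pseudokinase induced by stress (-0.74 and 1.21). Computed from log2 CPM over 19488 genes, the fold changes of the same columns correlated at r = -0.033, with a covariance of -0.0051. With all libraries simulated as unchanged, controls included, r was 0.484 and the covariance 0.011. Those libraries were drawn independently of each other, whereas the control column shCTRL VXN replicate 2 resembled the shDAT D columns. The 3 shared controls could not be split into 2 sets of at least 2 libraries.

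Between the labelled groups, shSLC6A3 DMSO and shCTRL DMSO did not separate. edgeR's quasi-likelihood test called 0 of 19488 genes and 0 of 914 repeat subfamilies (851 and 53 at an unadjusted p below 0.05), and DESeq2 called 0 of either (1223 unadjusted over both). EHMT2 had a log2 fold change of 0.08 (SE 0.31, edgeR adjusted p of 0.999), and without shCTRL DMSO replicate 3 it was -0.13. The biological coefficient of variation within labelled groups was 32.3%. In data simulated with that spread, edgeR recovered 81.8% of 4-fold, 11.9% of 2-fold and 0% of 1.5-fold changes. DESeq2 recovered 93.9%, 55.2% and 8.96% of them, and also called 54 of 20202 unchanged features. The simulated libraries were drawn independently, and changes were planted only in features with a mean of at least 1 CPM. The labelled groups instead held libraries of unlike expression, so these shares do not give the power of the labelled comparison. Of the 21 lists tested, 7 passed camera: immediate early genes (median log2 fold change -1.47), hypoxia (-0.62), leukocyte markers (-0.83), mesenchymal markers (-0.43) and interferon-stimulated genes (-0.27) toward lower, and chaperones (0.16) and lysosome (0.12) toward higher values. None passed with an estimated correlation, the lowest adjusted p being 0.434 with an estimated correlation, and none passed limma's fry. Both take the spread within the labelled groups, which held libraries of unlike expression, so these failures do not show that the lists were unchanged. Adjusted over the list alone, 11 immediate early genes and 0 members of the other 20 lists were called. FOS stood at 535, 509 and 7.23 CPM in shCTRL DMSO and at 7.39, 4.40 and 4.06 CPM in shSLC6A3 DMSO, so that shCTRL DMSO replicate 3 lay with the other group. The number of passing lists was 12 without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1. Of 28 repeat families and classes, 19 passed camera, all of them toward lower values, 0 with an estimated correlation (lowest adjusted p = 0.258 with an estimated correlation) and 0 by fry. That count was 11 with shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 2 left out, and 12 with shSLC6A3 DMSO replicate 3 or shCTRL VXN replicate 2 left out.

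Between the libraries labelled shCTRL VXN and shCTRL DMSO, 2 microRNA genes were lower. MIR6797 (ENSG00000276926.1, GRCh38 chromosome 19, 41869627 to 41869698, plus strand), which lies inside the ribosomal protein gene RPS19, had a log2 fold change of -2.82 (SE 0.26), and MIR6856 (ENSG00000277713.1, chromosome 9, 130626297 to 130626363, plus strand), inside FUBP3, one of -3.89 (SE 0.36), each with an edgeR adjusted p of 0.0458. MIR6797 stood at 2.54, 1.95 and 2.44 CPM in shCTRL DMSO, 2.89, 1.80 and 2.03 CPM in shSLC6A3 DMSO and 0.295, 0.290 and 0.387 CPM in shCTRL VXN. MIR6856 held 25, 23 and 20 counts in shCTRL DMSO, 25, 22 and 24 in shSLC6A3 DMSO and 1, 1 and 2 in shCTRL VXN. RNA-seq libraries of this kind do not capture mature microRNAs well, RPS19 and FUBP3 themselves were at 0.17 and -0.15, and the shCTRL VXN libraries carry library numbers from a separate range. Those were the only calls of edgeR among 19488 genes (360 unadjusted), with 0 of 914 repeat subfamilies (16 unadjusted), while DESeq2 called 20 genes and 0 subfamilies (452 unadjusted over both). Left out singly, each of the 9 libraries ended both calls, as did fitting the 6 libraries alone (0 genes), while the log2 fold changes stayed between -2.97 and -2.74 for MIR6797 and between -4.23 and -3.57 for MIR6856 without single libraries. EHMT2 was at 0.08 (SE 0.31) and not called by edgeR, and without shCTRL DMSO replicate 3 at -0.13. With p adjusted over the list alone, 0 members of the 21 lists were called there. None of the 21 lists passed camera, with the preset or an estimated correlation, or fry, but 10 passed without shCTRL DMSO replicate 3, 1 without shCTRL VXN replicate 1, 5 without shCTRL VXN replicate 2 and 6 without shCTRL VXN replicate 3. Of 28 repeat families and classes, 13 passed camera (8 without shCTRL DMSO replicate 3), among them Alu with a median of 0.18 and L1 with -0.11. None passed with an estimated correlation (Alu and L1 each with an adjusted p = 0.292 with an estimated correlation), and 1 passed fry.

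The libraries labelled shCTRL VXN and shSLC6A3 DMSO gave 0 gene calls by edgeR (1612 unadjusted) and 0 repeat calls (122 unadjusted), against 128 genes and 9 subfamilies by DESeq2 (2135 unadjusted over both). Without shSLC6A3 DMSO replicate 1, edgeR called 43 genes. Across 19488 genes the fold changes of shSLC6A3 and VXN against their shared shCTRL DMSO libraries correlated at r = 0.156, with a covariance of 0.017. Simulated unchanged groups gave an r of 0.50 (SD 0.011 over 20 simulations) and a covariance of 0.054. These came from log2 CPM, not from edgeR fold changes, and all libraries, controls included, were drawn independently. The labelled controls held libraries of unlike expression, so observed and simulated values are not like for like. The observed r was 0.670 without shCTRL DMSO replicate 3, 0.305 without shCTRL VXN replicate 2, 0.243 without shCTRL VXN replicate 1, 0.081 without shSLC6A3 DMSO replicate 1 and -0.123 without shCTRL VXN replicate 3. No genes were called in both comparisons, and 3 controls cannot be split into 2 sets of at least 2.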

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

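All reruns of the deposited comparisons were chosen after the data were seen: edgeR, DESeq2 at a threshold of 0.05, the series covariate and left-out libraries. The other alternatives were fixed before. Of the alternative values, 226 were classed as same, 75 moved, 26 were weaker and 5 reversed. For counts, same means equal to the main count or close to it in ratio, so 0 against 0 is included. For fold changes it means that sign and call were kept. For the shared r it means within 0.211 of the main value, the SD over left-out libraries. The cause was not tested unless stated. For VXN against shCTRL, the count of 2 genes was 0 with upper quartile factors, 1 without a low-count filter, 0 with a stricter one, 0 with the 6 libraries alone, 0 with a replicate block and 20 with DESeq2. MIR6797 and MIR6856 kept their direction in these and without each library (-2.97 to -2.74 and -4.23 to -3.57). Where weaker, their edgeR adjusted p was 0.0560 with upper quartile factors, 0.0532 for MIR6856 without a filter, 0.0968 for MIR6797 with a stricter one, 0.401 with 6 libraries, and 0.266 and 0.317 with a replicate block. VXN against shSLC6A3 gave 2 genes with RLE factors and 128 genes and 9 repeat subfamilies with DESeq2. The shared r was 0.448 without a filter. Lists passing for shSLC6A3 were 0 with an estimated correlation and 0 with fry. Repeat families were 0 and 0 with an estimated correlation, 0 (shSLC6A3) and 1 (VXN) with fry, and 11 (shSLC6A3) with a replicate block. For shDAT D, edgeR on the same columns gave 0 genes higher, 0 lower, 0 repeats higher and 0 lower; with the library series as a covariate these were 784, 1510, 47 and 4.

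Without single libraries, genes for VXN ranged from 0 to 0, VXN against shSLC6A3 from 0 to 43 (43 without shSLC6A3 DMSO replicate 1), and shared r from -0.123 (without shCTRL VXN replicate 3) to 0.670 (without shCTRL DMSO replicate 3). Lists ranged from 7 to 12 (shSLC6A3; 12 without shCTRL DMSO replicate 3 or shSLC6A3 DMSO replicate 1) and from 0 to 10 (VXN; 10 without shCTRL DMSO replicate 3). Repeat families ranged from 11 to 20 (shSLC6A3; 11 without shCTRL DMSO replicate 3) and from 8 to 13 (VXN; 8 without shCTRL DMSO replicate 3). EHMT2 reversed: for shSLC6A3 it ranged from -0.13 (without shCTRL DMSO replicate 3) to 0.31, with -0.03 without shSLC6A3 DMSO replicate 2 and -0.08 without replicate 3. For VXN it ranged from -0.13 (without shCTRL DMSO replicate 3) to 0.25, with -0.08 without shCTRL VXN replicate 2. On the shDAT D columns, genes higher ranged from 0 to 2926 and lower from 0 to 4767, and repeats from 0 to 188 and 0 to 9, each highest without shCTRL VXN replicate 2. On the shCTRL V columns, genes ranged from 4372 to 5413 higher and 4793 to 5851 lower, and repeats from 88 to 197 higher and 28 to 39 lower. Of the 126 named features there, all kept their sign in the 6 leave-outs, and 120 to 123 were still called. Of the 57 named for shDAT D, 56 were still called without shCTRL VXN replicate 2, 5 without shCTRL DMSO replicate 1, where SLC6A3 changed sign, and 0 without any 1 of the other 4.

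Replicate numbers are only shared numbers: of 9 pairs across groups, 5 correlated above 0.1, from -0.80 to 0.94, and 4 of 9 libraries correlated best with one of their own number. SLC6A3 lies below the filter, so alternatives of filter, tool and block were not run for it. Other size factors and the compared libraries alone were run. Leaving out single libraries gave differences of -0.061 to -0.018 CPM (shSLC6A3) and -0.049 to -0.014 CPM (VXN).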

Other observations

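The gene groups in the first 2 paragraphs, and all tests of patterns except thinning, library series and overlapping genes, were chosen after the results were seen. In the authors' deposited table for shCTRL V, 18 of 35 replication-dependent histone genes were higher and 2 lower, with a median of 1.40, H2AC6 at 3.57 (SE 0.13), H2BC5 at 2.95 (SE 0.11) and H1-2 at 2.30 (SE 0.15). Near-identical histone copies share reads. How much histone mRNA these TruSeq RNA v2 libraries capture was not tested, so the values may not follow total histone mRNA. Neither this group nor its difference from the replication list was tested. For shDAT D, 0 of 2 with an adjusted p changed in the authors' deposited table. Of 13 mitochondrially encoded respiratory genes, 1 was higher and 5 lower for shCTRL V (MT-CO2 at -0.69, SE 0.11; MT-ND4 at -0.55, SE 0.10; MT-ND3 at 0.38, SE 0.06), and 3 were higher and 0 lower for shDAT D (MT-CO2 at 0.52, SE 0.12; MT-CO1 at 0.39, SE 0.12; MT-CO3 at 0.26, SE 0.10), in the authors' deposited tables. The others did not pass, and neither the group nor the difference between the tables was tested. Mitochondrial genes took 6.28, 6.27 and 5.40% of the counts in the shCTRL V columns, 6.07, 6.05 and 6.96% in the shDAT D columns and 5.35, 5.45 and 5.26% in the shCTRL D columns.

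LTR7, the promoter of the HERVH endogenous retrovirus, was at 0.49 (SE 0.19) for shCTRL V and at -0.55 (SE 0.22) for shDAT D, and LTR7Y at -1.10 (SE 0.18) for shCTRL V, in the authors' deposited tables. HERVH-int itself was at 0.43 (SE 0.26) and -0.28 (SE 1.66), with neither called in the authors' deposited tables. EGR1, an immediate early transcription factor, stood at 936, 901 and 81.9 CPM in the libraries labelled shCTRL DMSO, 82.4, 64.3 and 64.2 CPM in shSLC6A3 DMSO, and 606, 883 and 68.7 CPM in shCTRL VXN. PFN1P1, a profilin pseudogene, had a log2 fold change of -1.87 (SE 0.23, edgeR adjusted p of 0.183) for VXN against shCTRL DMSO and -2.18 (SE 0.23, edgeR adjusted p of 0.0742) against shSLC6A3 DMSO.

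In each labelled group, some libraries differed more from each other than from libraries of other groups. After all libraries were thinned to 30251364 counts, shCTRL DMSO replicate 3 still reached at most r = 0.896 with the other 2 of its group, which argues against depth. Base means recomputed from the deposited counts differed from the authors' deposited tables by at most 4.80e-10, which argues against tables made from other counts. The labelled groups gave only 1.41% of the p-values in the authors' deposited table for shDAT D, so labels and table columns disagree. Whether samples were mislabelled in one source or columns misassigned in the other stays open, and no biological explanation was tested.

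The library labelled shCTRL VXN replicate 2 stood apart from the other 2 shCTRL D columns. Were the library series the whole cause, the deviations of the shCTRL VXN libraries would go together, but their lowest r was 0.00936 (middle 0.240, highest 0.269, 11661 genes). Its deviation followed that of shCTRL DMSO replicates 1 and 2 (shDAT D columns) with a slope of 1.01 (r = 0.945), though both subtract the same 2 columns, which pushes the slope up. Its r was 0.997 with shCTRL DMSO replicate 1 and 0.975 with shSLC6A3 DMSO replicate 2. Why this library resembles the shDAT D columns stays open, and no biological explanation was tested.

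MIR6797 and MIR6856 were lower in the libraries labelled shCTRL VXN. Over 235 tested microRNA genes the median log2 fold change was 0.11 (SD 0.69, 91 lower), which argues against a lower yield of short transcripts as a whole. The overlapping genes RPS19 and FUBP3 were at 0.17 and -0.15, which argues against a fall of these genes as a whole. Their reads over the short microRNA intervals were not compared, so such reads are not excluded as the cause. The VXN label and the library series coincide, so under the labels treatment and series cannot be told apart for these 2 genes. In the columns of the deposited tables the shCTRL VXN libraries each fall in a different trio. Under that grouping they share the series and not the condition.

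Each set of 6 libraries has 10 splits into 3 and 3, which cannot give a share under 0.05. Where the real count was 0, all 10 splits were as large in advance, so those results say nothing about the grouping. For genes, 10 of 10 splits were as large for shSLC6A3 against shCTRL (real 0, highest other 0), 1 for VXN against shCTRL (2 and 0) and 10 for VXN against shSLC6A3 (0 and 0), by edgeR. For repeats, 10 of 10 were as large in each of the 3 comparisons (0 and 0). For gene lists, 6 were as large for shSLC6A3 (7 and 14) and 10 for VXN (0 and 14), and for repeat families 2 (19 and 21) and 1 (13 and 11). On the table columns, 10 were as large for shDAT D (0 and 11, the 11 with shCTRL DMSO replicates 1 and 2 and shCTRL VXN replicate 2 on one side) and 1 for shCTRL V (10927 and 0), by edgeR.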
